A study of Mus musculus with 12 samples.

How the data were processed

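RNA was measured in 12 libraries of MMTV-NIC mouse breast cancer cells, 3 each of AXL WT and AXL KO cells held in 21% oxygen (normoxia) or 1% oxygen (hypoxia). Total RNA was isolated with RNeasy columns and sequenced on an Illumina HiSeq instrument. Per the submitters' processing notes, the authors checked reads with FastQC 0.11.5, aligned them with STAR 2.5.1b to mouse GRCm38 (Ensembl release 93), counted them with featureCounts 1.4.6 and used DESeq2 1.12.3. Per the file headers, the counting program was featureCounts 1.6.0, and the reason for the difference is not given in the sources used here. The deposited values are counts: per the file headers, fragments with both ends mapped were counted once per gene, reverse stranded (strand setting 2), without chimeric fragments and without fragments that mapped to more than 1 place.

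Groups and replicate numbers were taken from the sample titles. In 6 samples the genotype tag follows the oxygen level and contradicts the title, so that tag was not used. The labels give no hypoxia duration, no number of knockout clones and no origin of the replicates. Nothing says that the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. No library was left out of the principal results.

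The files hold 54232 genes. Symbols of 54165 were taken from GENCODE M21 by Ensembl gene ID, and 67 stayed unnamed. Of the named genes 52910 (97.7%) have the same start and end in both sources, and printed coordinates are those of the deposited files (GRCm38). Gene totals ran from 45297267 to 58775422 counts per library. At that depth 3 counts over a group lie below 0.1 CPM, and genes with few counts are treated apart, as described next.

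Counts were analysed with edgeR 4.0.16 in R 4.3.3. The function filterByExpr kept 16767 genes and removed 37465, TMM factors scaled the libraries, and a quasi-likelihood model with robust dispersion and 1 mean per group was fitted to all 12 libraries (8 residual degrees of freedom, common biological coefficient of variation 0.201). The 5 contrasts were AXL KO against WT in hypoxia, the same in normoxia, hypoxia against normoxia in AXL WT, the same in AXL KO, and the interaction. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 (edgeR), and every gene p printed is this adjusted p unless another tool is named. Values after ± are standard errors for log2 fold changes, computed as the absolute log2 fold change over the square root of F, and standard deviations of 3 libraries for CPM. CPM use TMM scaling. Where the lower group had 0 counts the fold is given as at least N-fold, with a floor of 3 counts over that group, and where it had 1 to 3 counts as a ratio of summed counts with its 95% counting interval. These floors and intervals cover counting error only, and none were computed for the interaction.

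The contrasts, tests, alternatives and 29 gene lists with 562 genes were chosen before the data were examined. The lists are HIF glycolysis, Other HIF targets, HIF machinery, TAM receptors and ligands, Mesenchymal, Epithelial, Mammary luminal, Basal and myoepithelial, Collagens and matrix, Cytokines and chemokines, Interferon-stimulated, MHC class I presentation, DNA replication, Mitosis, Cholesterol synthesis, Amino-acid stress (ATF4), ER chaperones (UPR), OXPHOS nuclear, Mitochondrially encoded, Ribosomal proteins, Replication-dependent histones, ERBB receptors and ligands, YAP targets, p53 targets, Immediate early, and Leukocyte, Fibroblast, Endothelial and Adipocyte markers. They were tested with camera (limma 3.58.1, preset correlation 0.01, adjusted over the 29 lists), and again with camera at an estimated correlation and with fry. Members called when p-values were adjusted over the list alone were also counted.

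Axl was always named. In each 2-group contrast the 8 higher and 8 lower protein-coding genes of largest log2 fold change were named that had adjusted p under 0.05, at least 10 CPM in the higher group and no overlap between libraries. For the interaction these were 6 and 6, without the rule on overlap. Up to 4 members per list with the smallest p were also named, and a named gene could be followed into other contrasts. Some genes that met these rules are not reported here.

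Principal components used log2 CPM with a prior count of 2, and list levels per library used the median of log2(CPM + 1). Alternatives chosen in advance were RLE size factors, library size alone, no filter, a strict filter (5 CPM in 3 libraries), DESeq2 1.42.0, limma-voom, the replicate number as a block, the 6 compared libraries alone, a minimum fold of 2, and each library left out in turn. A pair of further alternatives was chosen after seeing the data: voom with a quality weight per group, and AXL WT hypoxia libraries 2 and 3 left out. Group labels were also reassigned, in all 10 splits of 3 against 3 and in 100 drawn splits for the interaction. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

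The edgeR test was tested on simulated data in which few genes were changed, 194 to 196 per 2-group contrast and 390 or 392 in the interaction. With the same spread in all groups (16195 genes simulated), 6.06% of calls were false for AXL KO against WT in hypoxia, 7.02% for the same in normoxia, 5.29% for hypoxia in AXL WT, 6.02% for hypoxia in AXL KO and 5.39% for the interaction. It recovered 57.7%, 63.9%, 64.9%, 60.8% and 25.3% of 2-fold changes and 100%, 98%, 99%, 98% and 90.4% of 4-fold changes in these contrasts.

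With the spread that each group had in the data (16203 genes simulated), 73% of the 534 calls for AXL KO against WT in hypoxia and 67.4% of the 432 calls for hypoxia in AXL WT were false. At the p cutoffs of the data, 12.5% and 12.1% of unchanged genes were called there. Shares of false calls depend on the number of changed genes, and far more genes were called in the data than were changed here. The shares given in this part therefore do not carry over to the calls of the data. No call was false among 119 for AXL KO against WT in normoxia and 123 for hypoxia in AXL KO, and 7.77% were false for the interaction. Recovery of 2-fold changes was 51%, 26.5%, 51%, 36.5% and 17.5%, and of 4-fold changes 96.9%, 94.9%, 92.9%, 89.8% and 73.5%, in the order used above. Standard errors and p-values of contrasts with AXL WT hypoxia are therefore too small. Voom with a weight per group made 22% and 17.6% false calls in those contrasts, 7.04% and 4.64% in the others and 12.9% in the interaction. It recovered 29.2% and 27.6% of 2-fold changes in those contrasts, fewer than edgeR, and 88.8%, 90.6% and 28.9% in normoxia, in AXL KO and in the interaction, more than edgeR. Its counts stand beside the edgeR counts.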

Results

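The libraries came from cells of mammary tumours driven by an activated Neu (ErbB2), with or without AXL, a receptor tyrosine kinase of the TAM family, in 21% or 1% oxygen. Counts in genes totalled 46635155, 45297267 and 48854016 in AXL WT normoxia and 47417322, 46494077 and 46269167 in AXL WT hypoxia. They totalled 55579433, 57574352 and 58775422 in AXL KO normoxia, and 47965628, 51189977 and 52581702 in AXL KO hypoxia. Libraries of the same group all differed by more than sampling noise, with a chi-square per degree of freedom of 5.02 to 37.2 in 3 groups. In AXL WT hypoxia it was 403 between replicates 1 and 2, 226 between 1 and 3 and 120 between 2 and 3.

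Axl was read 51682, 47960 and 57291 times in AXL WT normoxia and 23077, 19395 and 28495 times in AXL WT hypoxia. It was read 164, 189 and 200 times in AXL KO normoxia and 86, 105 and 78 times in AXL KO hypoxia. Axl (ENSMUSG00000002602, chromosome 7, 25757273 to 25788705) therefore stood at 934 ± 57.7, 519 ± 69.1, 3.22 ± 0.271 and 2.05 ± 0.319 CPM in these groups. It was lower in AXL KO by a log2 fold change of −8.18 ± 0.17 in normoxia (adjusted p = 2.03e-11) and −7.98 ± 0.17 in hypoxia (adjusted p = 2.83e-11). Axl fell in hypoxia in AXL WT (−0.85 ± 0.12, adjusted p = 0.000106) and, at its low level, in AXL KO (−0.65 ± 0.14, adjusted p = 0.002). The responses of the genotypes differed by 0.2 ± 0.19 (adjusted p = 0.463).

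**Figure D1:**
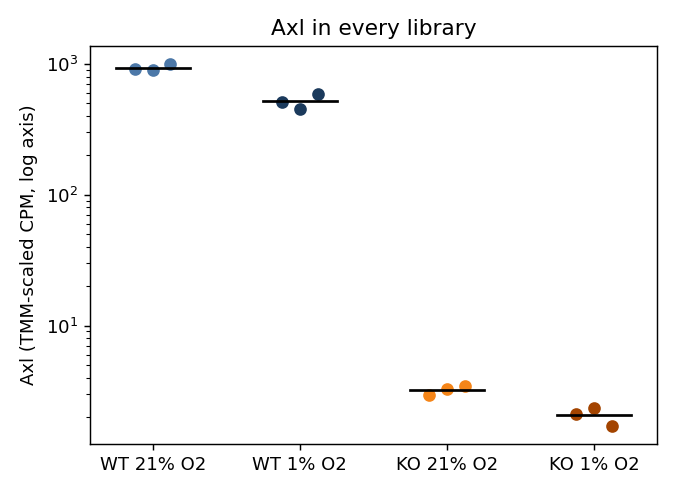
Axl in each library, as TMM-scaled CPM on a log axis, with points for libraries and bars for group means. AXL KO libraries lie at 1.716 to 3.468 CPM and AXL WT libraries at 454.6 to 1000 CPM.

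The largest axis of the expression data separated the genotypes (60.3% of the variance) and the next separated the oxygen levels (25.8%). The AXL WT hypoxia libraries also lay apart from each other on axes 3 and 4 (8% and 2.5%). Their biological coefficient of variation was 0.4, against 0.0585 in AXL WT normoxia, 0.0895 in AXL KO normoxia and 0.0738 in AXL KO hypoxia. Ptgs2, which makes prostaglandin precursors, was the most abundant gene of AXL WT hypoxia replicates 2 and 3 (2.42% and 1.92% of counts). Erbb2 stood at 2410, 131 and 360 CPM in AXL WT hypoxia replicates 1, 2 and 3, and Ccn2, a YAP target, at 2940, 17 and 150 CPM. Ribosomal RNA, nuclear and mitochondrial counted together, made up 0.093%, 0.52% and 0.284% of counts in these 3 libraries and 0.088% to 0.131% in all others. All mitochondrial genes made up 0.959%, 1.524% and 1.338% of counts in AXL WT hypoxia replicates 1, 2 and 3. Mitochondrial coding genes made up 0.867%, 1.004% and 1.054%. The gap between them matches the ribosomal share, which was thus nearly all mitochondrial. With library size alone as the scaling, the median log2 fold change of all genes moved from −0.041 to −0.208 for AXL KO against WT in hypoxia and from −0.03 to −0.285 in normoxia. It moved from −0.023 to −0.318 for hypoxia in AXL WT, from −0.026 to −0.23 for hypoxia in AXL KO and from −0.025 to 0.065 for the interaction.

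**Figure D2:**
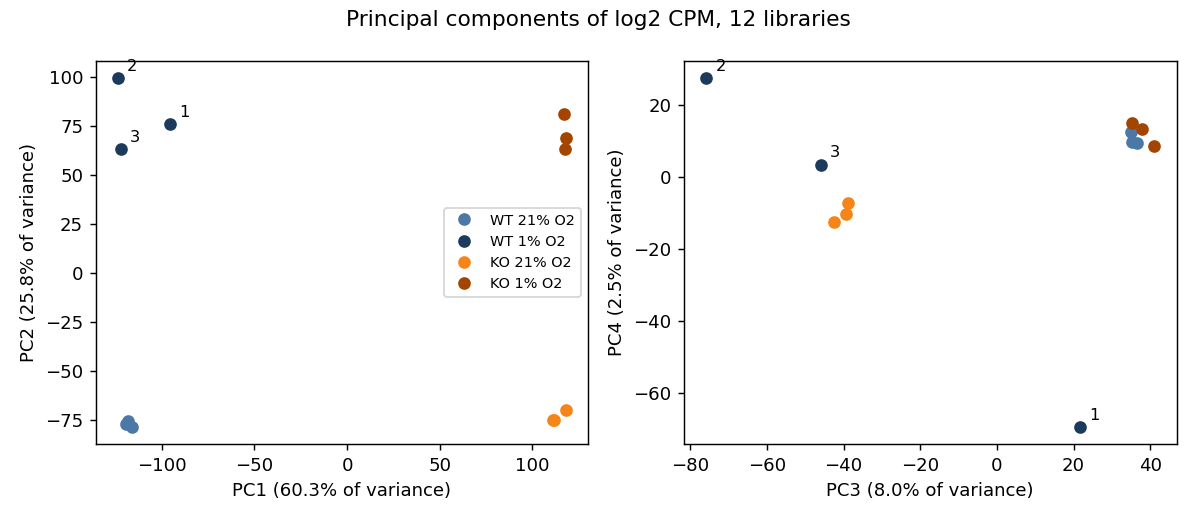
Principal components of log2 CPM, 1 point per library coloured by group, with axes in component units and the AXL WT hypoxia replicates numbered. Component 1 places AXL WT at −123.57 to −95.57 and AXL KO at 111.33 to 118.1, and component 3 places AXL WT hypoxia replicates 1, 2 and 3 at 21.69, −75.76 and −45.83.

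How AXL KO and WT cells differ in 1% oxygen is the question that the series names as its aim. In hypoxia AXL KO cells held more RNA of Other HIF targets, p53 targets and Collagens and matrix genes as lists, and these calls were lost with an estimated correlation. Single genes that were lower in AXL KO included Cxcl1, Cxcl5, Krt14, Sox10, Cdkn2a and Cdkn2b, while the cytokine and basal lists went both ways and were not called. The HIF glycolysis genes, which rise strongly in hypoxia in both genotypes, showed no shared direction between them.

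Other HIF targets were higher in AXL KO (22 rose, 1 fell and 9 were not called of 32 measured, or 23 and 1 adjusted over the list alone; median log2 fold change 0.78). The camera adjusted p was 3.14e-05, but adjusted p = 0.525 with an estimated correlation. They included the collagen-modifying enzymes Plod1 (1.87 ± 0.1, adjusted p = 1.65e-08) and Plod2 (ENSMUSG00000032374, chromosome 9, 92542223 to 92608428, 0.51 against 1840 CPM, 11.83 ± 0.47, adjusted p = 2.52e-09). Lox, which crosslinks collagen, stood at 0.0737 against 1240 CPM (14.0 ± 0.25, adjusted p = 1.25e-11), and the carbonic anhydrase Car9 rose as well (3.28 ± 0.26, adjusted p = 8.33e-07). Of the HIF glycolysis genes 6 rose and 6 fell of 24 (6 and 5 over the list alone). Their camera adjusted p was 0.846, with a median of −0.07 and a mean of 0.12. Gapdh (1.01 ± 0.1, adjusted p = 3.54e-06) and Pdk1, which restrains pyruvate oxidation (1.41 ± 0.15, adjusted p = 9.7e-06), rose, while Pgm2 fell (−1.05 ± 0.11, adjusted p = 8.14e-06).

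The p53 targets were higher in AXL KO (13 rose, 2 fell and 2 were not called of 17, and the same over the list alone). Their median was 1.25 (camera adjusted p = 0.00257, but adjusted p = 0.109 with an estimated correlation). Among them were Perp, a desmosome gene (ENSMUSG00000019851, chromosome 10, 18845020 to 18857073, 92.1 against 1210 CPM, 3.71 ± 0.16, adjusted p = 4.96e-09) and the death gene Bbc3 (2.36 ± 0.18, adjusted p = 6.43e-07). Zmat3 (1.42 ± 0.11, adjusted p = 7.18e-07) and Ccng1 (1.41 ± 0.12, adjusted p = 1.57e-06) rose as well. Collagens and matrix genes were also higher as a list (15 rose, 7 fell and 5 were not called of 27, and the same over the list alone). Their median was 1.19 (camera adjusted p = 0.0193, but adjusted p = 0.643 with an estimated correlation). That call ended without AXL WT hypoxia replicate 2 (adjusted p = 0.0682) and with the replicate number as a block (adjusted p = 0.122). Timp3, a protease inhibitor (ENSMUSG00000020044, chromosome 10, 86300372 to 86349506, 1.67 against 677 CPM, 8.66 ± 0.28, adjusted p = 5.89e-10), rose. So did Postn (7.57 ± 0.23, adjusted p = 3.43e-10) and Col1a2 (7.55 ± 0.32, adjusted p = 4.3e-09). The basement membrane gene Nid1 was higher in AXL KO with a ratio of 12600 (interval 2270 to 499000).

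Gas6, the ligand of AXL, had no count in AXL WT hypoxia and 34.8 CPM in AXL KO hypoxia, at least 1580-fold more (ENSMUSG00000031451, chromosome 8, 13465374 to 13494490). Pros1, a ligand of other TAM receptors, fell (−3.55 ± 0.46, adjusted p = 4.04e-05). Of the 5 TAM receptors and ligands 1 rose and 3 fell (camera adjusted p = 0.353). Of the Mesenchymal genes 10 rose and 5 fell of 17 (camera adjusted p = 0.109, or 0.0387 without AXL KO hypoxia replicate 1). Fibronectin, Fn1 (ENSMUSG00000026193, chromosome 1, 71585520 to 71653200, 3.78 ± 0.37, adjusted p = 4.32e-06), and Sparc (2.53 ± 0.19, adjusted p = 3.99e-07) rose. Tenascin C, Tnc, fell (−5.1 ± 0.44, adjusted p = 1.53e-06). Epithelial genes went both ways (5 rose and 7 fell of 19, camera adjusted p = 0.342). Cdh1, the E-cadherin gene (−2.76 ± 0.32, adjusted p = 1.76e-05), and Cldn4, a tight junction gene (−2.52 ± 0.23, adjusted p = 2.25e-06), fell. Of the Basal and myoepithelial genes 4 rose and 3 fell of 10 (4 and 4 over the list alone, camera adjusted p = 0.126). Sox10 (−6.67 ± 0.26, adjusted p = 2.52e-09), the smooth muscle kinase Mylk (−6.67 ± 0.25, adjusted p = 1.38e-09) and the basal keratin Krt14 (−5.52 ± 0.38, adjusted p = 2.48e-07) were among those that fell.

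Cytokines and chemokines went both ways (8 rose and 14 fell of 25, camera adjusted p = 0.681). The neutrophil chemokines Cxcl5 (−4.61 ± 0.23, adjusted p = 1.58e-08) and Cxcl1 (−4.11 ± 0.28, adjusted p = 2.11e-07) fell. The alarmin Il33 rose (ENSMUSG00000024810, chromosome 19, 29925114 to 29960718, 6.02 ± 0.21, adjusted p = 1.06e-09). Amino-acid stress genes had 8 rises and 10 falls of 24 (camera adjusted p = 0.695). Slc7a11, a cystine transporter (−4.81 ± 0.35, adjusted p = 3.92e-07), and Asns, which makes asparagine (−3.03 ± 0.17, adjusted p = 4.52e-08), fell. Stc2 rose (ENSMUSG00000020303, chromosome 11, 31357307 to 31370074, 3.83 ± 0.17, adjusted p = 6.35e-09). Of the Mitosis genes 17 rose and 2 fell of 24 (camera adjusted p = 0.126, or 0.0195 without AXL KO hypoxia replicate 1). Of the DNA replication genes 4 rose and 13 fell of 28 (camera adjusted p = 0.248). The spindle gene Nusap1 rose (1.71 ± 0.18, adjusted p = 7.48e-06) and the helicase gene Mcm5 fell (−1.86 ± 0.25, adjusted p = 5.51e-05). Ndufs1 of respiratory complex I fell (−1.16 ± 0.08, adjusted p = 3.42e-07), with 3 rises and 16 falls of 30 OXPHOS nuclear genes (camera adjusted p = 0.126).

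The other lists were not called in this contrast. Rises and falls were 4 and 2 of 10 for HIF machinery (adjusted p = 0.431), 5 and 4 of 13 for Mammary luminal genes (0.738), 7 and 13 of 25 for Interferon-stimulated genes (0.315) and 12 and 3 of 17 for MHC class I presentation (0.126). They were 7 and 9 of 23 for Cholesterol synthesis (0.794), 7 and 7 of 20 for ER chaperones (0.762) and 0 and 4 of 7 for Mitochondrially encoded genes (0.431). For Ribosomal proteins they were 12 and 5 of 32 (0.522), and for Replication-dependent histones 1 and 0 of 6 (0.711). The remaining counts were 3 and 2 of 10 for ERBB receptors and ligands (0.846), 7 and 2 of 16 for YAP targets (0.522) and 4 and 6 of 15 for Immediate early genes (0.711). Among markers of other cell types they were 2 and 3 of 7 for leukocytes (0.846), 0 and 5 of 7 for fibroblasts (0.126), 2 and 4 of 8 for endothelium (0.883) and 2 and 1 of 3 for adipocytes (0.126). Adjusted over the list alone, Mammary luminal genes had 5 and 5, MHC genes 13 and 3 and ERBB genes 3 and 1, and the others were unchanged. The medians of the Ribosomal proteins (0.15, or −0.01), HIF machinery (0.05, or −0.11) and Cholesterol synthesis (0.04, or −0.13) changed sign with library size alone. Median, mean and test did not all have the same sign for the HIF glycolysis, TAM, Mammary luminal, Cholesterol, ER chaperone, Immediate early, leukocyte and endothelial lists.

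Of the 8 genes higher in AXL KO by the naming rule, none had a count in AXL WT hypoxia. They were the membrane protease Mmp14 (ENSMUSG00000000957, chromosome 14, 54431612 to 54445364, 154 ± 17.6 CPM, at least 7020-fold higher), Wtip (at least 4700-fold) and the glypican Gpc4 (4210). The others were Setbp1 (4000), the scavenger receptor Colec12 (3450), Lrig3 (2560), Ppp1r3c (2500) and Prelid2 (2250). The lower genes were Adam22 (ENSMUSG00000040537, chromosome 5, 8072352 to 8368160, 451 ± 50.5 CPM in AXL WT, at least 19800-fold lower) and the neighbouring cell-cycle inhibitor genes Cdkn2b (at least 2770-fold, ENSMUSG00000073802, chromosome 4, 89306289 to 89311032) and Cdkn2a (2410, ENSMUSG00000044303, chromosome 4, 89274471 to 89294653). Next came Klhl4 (1170), Xlr (1140), Zfp334 (1090) and Sprr2e (941), and all of these had no count in AXL KO hypoxia. Gpr149 was lower with a ratio of 23900 (interval 8190 to 116000).

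Of 16767 genes tested, 10557 (63%) were called, 5016 higher and 5541 lower in AXL KO. With library size alone it was 4170 higher and 6481 lower, so that the share of higher calls moved from 47.5% to 39.2%. Because the AXL WT hypoxia libraries spread widely, the p-values are too small here. Voom with a weight per group called 8209 genes, and the 6 compared libraries alone gave 7696 calls. Without AXL WT hypoxia replicates 2 and 3 the count was 10426, of which 8428 were among the 10557, but that group then holds 1 library and the spread comes from the other groups, so this count does not test the p-values.

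The same genotypes in 21% oxygen show which differences were present without hypoxia. AXL KO cells already had higher levels of most HIF target genes, glycolytic and other, and of most ER chaperones. All measured genes of the DNA replication and Mitosis lists were lower. Higher matrix, p53 target and class I presentation genes, and lower interferon-stimulated genes, also marked AXL KO. All list calls of this contrast were lost with an estimated correlation.

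HIF glycolysis genes were higher in AXL KO normoxia (22 rose, 1 fell and 1 was not called of 24, and the same over the list alone). Their median was 1.02 (camera adjusted p = 4.81e-06, but adjusted p = 0.316 with an estimated correlation). Other HIF targets were higher too (26 rose, 0 fell and 6 were not called of 32, or 27 and 0 over the list alone). Their median was 1.71 (camera adjusted p = 1.37e-09, but adjusted p = 0.243 with an estimated correlation). Pfkfb3, which drives glycolytic flux, rose from 6.9 to 85 CPM (ENSMUSG00000026773, chromosome 2, 11471433 to 11554077, 3.62 ± 0.16, adjusted p = 4.62e-09). Pdk1 (2.32 ± 0.16, adjusted p = 1.65e-07), the prolyl hydroxylase of collagen P4ha2 (2.88 ± 0.12, adjusted p = 4.21e-09) and Lox (10.61 ± 0.22, adjusted p = 2.03e-11) rose too. Of the HIF machinery genes 6 rose and 1 fell of 10 (camera adjusted p = 0.0606). Epas1, the HIF-2α gene (4.23 ± 0.18, adjusted p = 4.62e-09), and Hif1a (1.19 ± 0.16, adjusted p = 4.49e-05) were among those that rose.

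Every DNA replication gene was lower (28 of 28 fell, and the same over the list alone). Their median was −2.37 (camera adjusted p = 8.76e-16, but adjusted p = 0.187 with an estimated correlation). The same held for the Mitosis genes (24 of 24 fell, and the same over the list alone). Their median was −1.76 (camera adjusted p = 7.52e-09, but adjusted p = 0.316 with an estimated correlation). The replicative helicase gene Mcm6 (330 against 43.1 CPM, −2.94 ± 0.16, adjusted p = 2.97e-08) and the polymerase gene Pole (−3.18 ± 0.18, adjusted p = 4.41e-08) fell. So did the spindle checkpoint gene Bub1 (−2.8 ± 0.18, adjusted p = 9.25e-08) and Birc5 (−2.25 ± 0.18, adjusted p = 7.36e-07). The p53 targets were higher (10 rose, 2 fell and 5 were not called of 17, and the same over the list alone). Their median was 0.81 (camera adjusted p = 0.00487, but adjusted p = 0.125 with an estimated correlation). They included Bbc3 (2.49 ± 0.18, adjusted p = 3.4e-07) and the death receptor genes Fas (2.83 ± 0.19, adjusted p = 1.3e-07) and Eda2r (6.09 ± 0.4, adjusted p = 1.21e-07).

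ER chaperones were higher (16 rose, 0 fell and 4 were not called of 20, or 17 and 0 over the list alone). Their median was 0.93 (camera adjusted p = 0.000153, but adjusted p = 0.504 with an estimated correlation). Xbp1, a transcription factor of the unfolded protein response (ENSMUSG00000020484, chromosome 11, 5520659 to 5525893, 1.23 ± 0.09, adjusted p = 2.24e-07), and Sel1l, which serves the removal of misfolded proteins (2.03 ± 0.11, adjusted p = 2.49e-08), rose. Class I presentation genes were higher (12 rose, 2 fell and 3 were not called of 17, or 13 and 3 over the list alone). Their median was 0.83 (camera adjusted p = 0.0217, but adjusted p = 0.358 with an estimated correlation). Among them were H2-T23 (3.31 ± 0.17, adjusted p = 1.71e-08) and H2-K1 (1.26 ± 0.1, adjusted p = 4.71e-07). Interferon-stimulated genes were lower (2 rose, 14 fell and 9 were not called of 25, and the same over the list alone). Their median was −0.76 (camera adjusted p = 0.0217, but adjusted p = 0.66 with an estimated correlation). The antiviral gene Oasl1 was lower (−5.08 ± 0.42, adjusted p = 8.48e-07).

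Mesenchymal genes were higher (12 rose, 3 fell and 2 were not called of 17, and the same over the list alone). Their median was 1.29 (camera adjusted p = 0.00187, but adjusted p = 0.125 with an estimated correlation). Collagens and matrix genes were higher too (15 rose, 6 fell and 6 were not called of 27, or 15 and 7 over the list alone). Their median was 0.91 (camera adjusted p = 0.000764, but adjusted p = 0.316 with an estimated correlation). Fn1 (606 against 16700 CPM, 4.78 ± 0.39, adjusted p = 7.21e-07) and Mmp14 (12.33 ± 0.24, adjusted p = 2.3e-10) rose. So did Col6a1 (3.44 ± 0.13, adjusted p = 1.52e-09) and Timp3 (10.94 ± 0.32, adjusted p = 2.69e-10). Mammary luminal genes were higher (9 rose, 1 fell and 3 were not called of 13, and the same over the list alone). Their median was 1.34 (camera adjusted p = 0.031, but adjusted p = 0.243 with an estimated correlation). Members called included the milk protein gene Ltf (5.09 ± 0.37, adjusted p = 3.32e-07) and the luminal regulator Gata3 (1.36 ± 0.15, adjusted p = 8.8e-06). Of the Epithelial genes 3 rose and 12 fell of 19 (adjusted p = 0.0606). The keratin Krt7 (−2.83 ± 0.29, adjusted p = 5.75e-06) and Grhl2, a regulator of epithelial junctions (−6.02 ± 0.63, adjusted p = 6.33e-06), fell.

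Cytokines and chemokines were higher (11 rose, 4 fell and 10 were not called of 25, and the same over the list alone). Their median was 0.83 (camera adjusted p = 0.0217, but adjusted p = 0.316 with an estimated correlation). Il33 rose from 1.2 to 544 CPM (8.83 ± 0.23, adjusted p = 1.23e-10). Spp1, which encodes osteopontin, rose from 2360 to 20100 CPM (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050, 3.09 ± 0.14, adjusted p = 6.14e-09). Tgfb1 rose as well (2.67 ± 0.19, adjusted p = 2.9e-07). Gas6 was higher with a ratio of 20200 (interval 3630 to 799000). Mertk, another TAM receptor, rose (2.36 ± 0.17, adjusted p = 3.11e-07), with 2 rises and 2 falls among 5 TAM genes (adjusted p = 0.724). Egfr rose (6.98 ± 0.51, adjusted p = 3.09e-07), with 3 rises and 3 falls among 10 ERBB receptors and ligands (adjusted p = 0.661). The immediate early gene Egr1 rose (ENSMUSG00000038418, chromosome 18, 34859823 to 34864984, 3.01 ± 0.17, adjusted p = 3.65e-08), with 7 rises and 2 falls of 15 (adjusted p = 0.155).

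In the remaining lists, none called, rises and falls were 2 and 3 of 10 for Basal and myoepithelial genes (adjusted p = 0.549), 12 and 4 of 23 for Cholesterol synthesis (0.112) and 10 and 8 of 24 for Amino-acid stress (0.661). They were 5 and 12 of 30 for OXPHOS nuclear genes (0.442), 1 and 0 of 7 for Mitochondrially encoded genes (0.724), 3 and 18 of 32 for Ribosomal proteins (0.0606), 2 and 1 of 6 for histones (0.612) and 7 and 4 of 16 for YAP targets (0.51). Of other cell types they were 3 and 2 of 7 for leukocyte markers (0.729), 1 and 4 of 7 for fibroblast markers (0.859), 1 and 2 of 8 for endothelial markers (0.879) and 1 and 1 of 3 for adipocyte markers (0.196). Adjusted over the list alone, Cholesterol synthesis had 12 and 5 and fibroblast markers 1 and 5, and the others were unchanged. The medians of Amino-acid stress (0.21, or −0.04), Mitochondrially encoded genes (0.14, or −0.11) and YAP targets (0.21, or −0.05) changed sign with library size alone. The signs of median, mean and test differed for the Basal, ERBB, leukocyte and endothelial lists.

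The higher genes by the naming rule had no count in AXL WT normoxia, or 1 in the case of Colec12. They were Ckap4, a protein of the ER (ENSMUSG00000046841, chromosome 10, 84526305 to 84534062, at least 7440-fold), and the cyclin gene Ccnd2 (6090, ENSMUSG00000000184, chromosome 6, 127125162 to 127152193). Next came the cathepsin Ctsz (5870), Gpc4 (5760), the BMP-family gene Gdf6 (5610), Fndc1 (2860), Fam189a2 (2540) and Colec12 (ratio 34300, interval 6160 to 1360000). The lower genes were Psg20 (at least 1660-fold), Zfp251 (1510), Xlr (1390), Cdkn2b (1380), Klhl4 (1190), Cyp2d22 (1120), Pex5l (1120) and Gpr149 (ratio 11600, interval 3210 to 95600).

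Of 16767 genes, 10009 (59.7%) were called, 4976 higher and 5033 lower. With library size alone it was 3717 higher and 6667 lower, so that the share of higher calls moved from 49.7% to 35.8%. Voom with a weight per group called 12914 genes and the 6 compared libraries alone 12610. In data simulated with the spread of each group, edgeR recovered 26.5% of 2-fold changes in this contrast and voom with weights 88.8%. The genotype differences at both oxygen levels were alike in sign. At both levels 7269 genes were called, 3324 higher and 3341 lower at both (1489 and 1663 by chance) and 604 opposite. The fold changes correlated across genes (r = 0.826, rho = 0.685). The comparisons share no library, and genes are not independent replicates. Medians of these fold changes differed between chromosomes, for example chromosome 12 (0.47 in hypoxia, 0.46 in normoxia) and chromosome 3 (−0.47 and −0.42).

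**Figure D3:**
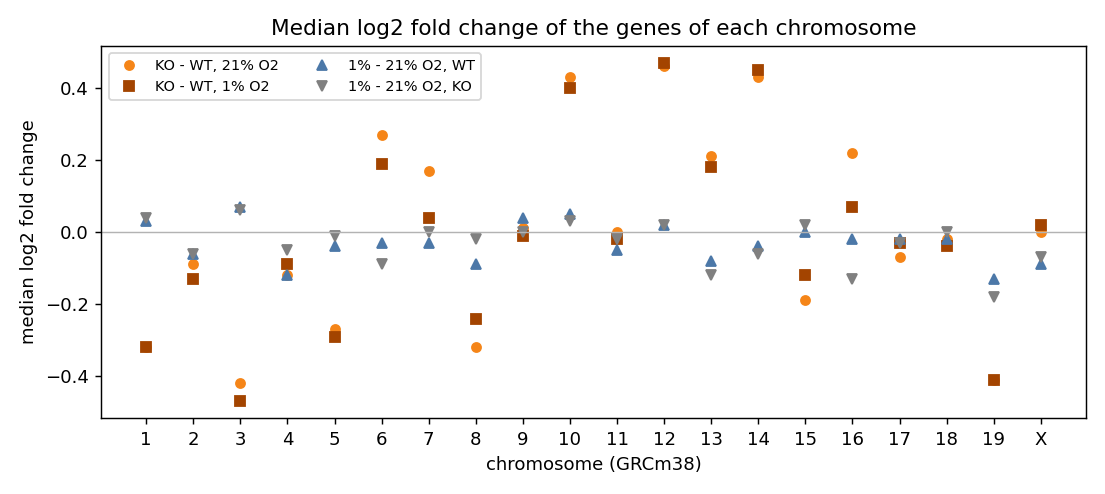
Median log2 fold change of the genes on each chromosome (points) in the 4 contrasts of a pair of groups (colours). Chromosome medians of AXL KO against WT had an SD of 0.265 in hypoxia and 0.278 in normoxia, and those of hypoxia against normoxia 0.0548 in AXL WT and 0.0618 in AXL KO.

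What 1% oxygen changed in cells that have AXL comes next. AXL WT cells raised HIF targets, glycolytic and other, together with matrix, mesenchymal and immediate early genes. They lowered nearly all measured DNA replication and Mitosis genes, and most genes of amino-acid stress and interferon stimulation. Genes scarcely read in normoxia, such as Nos2 and Sprr2e, appeared. With an estimated correlation the calls of the HIF glycolysis list and Other HIF targets held, and those of the other lists were lost.

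HIF glycolysis genes rose (23 rose, 0 fell and 1 was not called of 24, and the same over the list alone). Their median was 2.32 (camera adjusted p = 3.9e-35, and adjusted p = 0.0203 with an estimated correlation). Other HIF targets rose as well (26 rose, 2 fell and 4 were not called of 32, or 28 and 2 over the list alone). Their median was 2.49 (camera adjusted p = 5.4e-31, and adjusted p = 0.0203 with an estimated correlation). Pfkfb3 rose from 6.9 to 802 CPM (6.86 ± 0.18, adjusted p = 2.47e-09) and the glucose transporter Slc2a1 by 2.75 ± 0.12 (adjusted p = 2.59e-08). Ankrd37 rose by 4.97 ± 0.16 (adjusted p = 4.95e-09), P4ha2 by 4.46 ± 0.13 (adjusted p = 4e-09, ENSMUSG00000018906, chromosome 11, 54100095 to 54131665) and Car12 by 5.12 ± 0.21 (adjusted p = 2.43e-08). Of the HIF machinery genes 6 rose and 2 fell of 10 (adjusted p = 0.124). Hif1a (2.34 ± 0.16, adjusted p = 5.15e-07) and Cited2, which restrains HIF (1.7 ± 0.12, adjusted p = 6.24e-07), rose.

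DNA replication genes fell (1 rose, 25 fell and 2 were not called of 28, or 1 and 26 over the list alone). Their median was −2.23 (camera adjusted p = 4.85e-16, but adjusted p = 0.24 with an estimated correlation). Mitosis genes fell too (24 of 24 fell, and the same over the list alone). Their median was −2.34 (camera adjusted p = 3.1e-17, but adjusted p = 0.258 with an estimated correlation). Mcm6 (−2.63 ± 0.16, adjusted p = 2.03e-07) and Pole (−3.38 ± 0.19, adjusted p = 1.03e-07) fell. So did Kif11, a spindle motor (107 to 8.55 CPM, −3.64 ± 0.23, adjusted p = 2.62e-07), and Nusap1 (−3.2 ± 0.19, adjusted p = 1.59e-07). Amino-acid stress genes fell (3 rose, 15 fell and 6 were not called of 24, or 3 and 16 over the list alone). Their median was −1.41 (camera adjusted p = 0.00073, but adjusted p = 0.395 with an estimated correlation). They included Shmt2 of mitochondrial serine use (−2.85 ± 0.16, adjusted p = 1.1e-07) and Pycr1, which makes proline (−3.53 ± 0.25, adjusted p = 5.71e-07). The stress gene Nupr1 rose (3.47 ± 0.22, adjusted p = 2.82e-07).

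Mesenchymal genes rose (12 rose, 2 fell and 3 were not called of 17, and the same over the list alone). Their median was 0.82 (camera adjusted p = 0.00292, but adjusted p = 0.0629 with an estimated correlation). Among them were Snai2 (2.42 ± 0.26, adjusted p = 1.1e-05) and Zeb1 (1.4 ± 0.14, adjusted p = 5.14e-06), both repressors of E-cadherin, and Ncam1 (2.12 ± 0.09, adjusted p = 2.92e-08). Collagens and matrix genes rose (16 rose, 4 fell and 7 were not called of 27, and the same over the list alone). Their median was 1.19 (camera adjusted p = 0.00292, but adjusted p = 0.395 with an estimated correlation). An example was Col1a1 (4.25 ± 0.28, adjusted p = 3.06e-07). Immediate early genes rose (8 rose, 3 fell and 4 were not called of 15, or 9 and 3 over the list alone). Their median was 1.28 (camera adjusted p = 0.00622, but adjusted p = 0.339 with an estimated correlation). Jun (2.86 ± 0.14, adjusted p = 4.54e-08) and Ier3 (3.42 ± 0.12, adjusted p = 5.15e-09) rose and Egr1 fell (−1.89 ± 0.16, adjusted p = 2.39e-06).

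Interferon-stimulated genes fell (3 rose, 17 fell and 5 were not called of 25, and the same over the list alone). Their median was −1.36 (camera adjusted p = 0.00622, but adjusted p = 0.587 with an estimated correlation). They included Parp14 (−2.71 ± 0.25, adjusted p = 3.11e-06) and the RNA sensor gene Ifih1 (−2.56 ± 0.22, adjusted p = 1.95e-06). Of the Cytokines and chemokines 11 rose and 5 fell of 25 (adjusted p = 0.27). Cxcl2 (3.15 ± 0.43, adjusted p = 6.87e-05) and Cxcl5 (2.2 ± 0.2, adjusted p = 3.81e-06) rose. The p53 targets went both ways (7 rose and 6 fell of 17, adjusted p = 0.493). Cdkn1a, which stops the cell cycle (1.91 ± 0.1, adjusted p = 5.47e-08), and Sesn1 (2.81 ± 0.13, adjusted p = 3.97e-08) rose. Mertk rose (2.44 ± 0.17, adjusted p = 5.54e-07) and so did Pros1 (2.56 ± 0.44, adjusted p = 0.000371). The 5 TAM genes had 2 rises and 2 falls (adjusted p = 0.703). The mitochondrial genes mt-Cytb (−1.77 ± 0.17, adjusted p = 4.33e-06) and mt-Nd5 (−1.65 ± 0.21, adjusted p = 3.98e-05) fell, with 1 rise and 4 falls of 7 (adjusted p = 0.295).

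In the remaining lists, none called, rises and falls were 5 and 6 of 19 for Epithelial genes (adjusted p = 0.989), 4 and 3 of 13 for Mammary luminal genes (0.977) and 5 and 1 of 10 for Basal and myoepithelial genes (0.332). They were 6 and 6 of 17 for MHC class I presentation (0.906), 8 and 6 of 23 for Cholesterol synthesis (0.493) and 6 and 0 of 20 for ER chaperones (0.389). They were 4 and 7 of 30 for OXPHOS nuclear genes (0.989), 0 and 5 of 32 for Ribosomal proteins (0.862), 2 and 1 of 6 for histones (0.645), 2 and 5 of 10 for ERBB receptors and ligands (0.745) and 5 and 5 of 16 for YAP targets (0.78). Of other cell types there were 3 and 2 of 7 for leukocyte markers (0.745), 1 and 2 of 7 for fibroblast markers (0.989), 5 and 0 of 8 for endothelial markers (0.232) and 1 and 1 of 3 for adipocyte markers (0.989). Adjusted over the list alone, Cholesterol synthesis had 8 and 7, OXPHOS 3 and 6 and Ribosomal proteins 0 and 4. With library size alone the ER chaperones turned to 2 rises and 5 falls (median 0.27, or −0.02), the Ribosomal proteins to 0 and 28 (median −0.02, or −0.33), OXPHOS genes to 2 and 17 and Epithelial genes to 5 and 10, and the median of the Mesenchymal genes moved from 0.82 to 0.51. The medians of Cholesterol synthesis (0.15, or −0.14), YAP targets (0.05, or −0.25), histones (0.22, or −0.08), MHC genes (0.02, or −0.29) and OXPHOS genes (0.01, or −0.28) changed sign with it too. The signs of median, mean and test differed for the TAM, Epithelial, MHC, OXPHOS, p53 and fibroblast lists.

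By the naming rule the higher genes were Sprr2e, a gene of the cornified envelope (no count in normoxia, at least 1200-fold), Prss35 (10.4 ± 1.03, adjusted p = 6.18e-06) and the nitric oxide synthase gene Nos2 (ENSMUSG00000020826, chromosome 11, 78920787 to 78960254, 0.0964 to 96.8 CPM, 9.95 ± 0.38, adjusted p = 1.68e-08). Next came the macrophage receptor gene Csf1r (ENSMUSG00000024621, chromosome 18, 61105572 to 61132149, 9.64 ± 1.21, adjusted p = 3.79e-05), Gper1 (8.8 ± 0.67, adjusted p = 8.73e-07), Bmp6 (8.56 ± 0.81), Sprr1a (8.32 ± 0.62) and Sprr2k (8.27 ± 1.45). Csf1r differed between the libraries, at 5.41, 145 and 41.1 CPM. Most of the others were uneven in AXL WT hypoxia too: Sprr2e stood at 21.9 ± 16.3 CPM, Prss35 at 164 ± 131, Gper1 at 217 ± 176, Bmp6 at 34.6 ± 29.7, Sprr1a at 134 ± 91.2 and Sprr2k at 13.6 ± 14.7. The lower genes were the integrin Itgb2 (−6.23 ± 0.39, adjusted p = 2.39e-07), Fam19a5 (−5.72 ± 0.25, adjusted p = 2.93e-08), Nr1h5 (−5.34 ± 0.28), Cdca7 (−4.95 ± 0.45, adjusted p = 3.12e-06) and Tril (−4.51 ± 0.44). Then followed the mitotic motor Kif15 (ENSMUSG00000036768, chromosome 9, 122951046 to 123018733, −4.25 ± 0.21, adjusted p = 5.21e-08), Sgk2 (−4.18 ± 0.33) and Shmt1 (−4.03 ± 0.27, adjusted p = 4.16e-07).

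Of 16767 genes, 10035 (59.8%) were called, 4895 higher and 5140 lower. With library size alone it was 3473 higher and 7001 lower, so that the share of higher calls moved from 48.8% to 33.2%. The spread of AXL WT hypoxia makes the p-values too small here as well. Voom with a weight per group called 7607 genes and the 6 compared libraries 7600. Without AXL WT hypoxia replicates 2 and 3 the count was 11533, with 1 library left in that group and the spread taken from the others.

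Cells without AXL were compared between the oxygen levels in the same way. AXL KO cells also raised HIF targets in hypoxia, and they raised ribosomal protein genes. They lowered ER chaperones, amino-acid stress genes, cytokines and mitochondrially encoded genes. DNA replication and Mitosis genes showed no shared fall. The list calls here were lost with an estimated correlation.

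HIF glycolysis genes rose (21 rose, 2 fell and 1 was not called of 24, and the same over the list alone). Their median was 1.31 (camera adjusted p = 8.75e-14, but adjusted p = 0.145 with an estimated correlation). Other HIF targets rose too (30 rose, 1 fell and 1 was not called of 32, and the same over the list alone). Their median was 1.95 (camera adjusted p = 7.84e-26, but adjusted p = 0.0512 with an estimated correlation). Pfkfb3 (85 to 1240 CPM, 3.87 ± 0.16, adjusted p = 2.82e-08) and Slc2a1 (1.98 ± 0.11, adjusted p = 1.95e-07) rose. So did the angiogenic gene Vegfa (ENSMUSG00000023951, chromosome 17, 46016993 to 46032369, 2.71 ± 0.13, adjusted p = 7.68e-08), Ankrd37 (3.42 ± 0.15, adjusted p = 4.12e-08) and P4ha2 (2.83 ± 0.12, adjusted p = 4.09e-08). Ribosomal proteins rose by small amounts (26 rose, 0 fell and 6 were not called of 32, or 27 and 0 over the list alone). Their median was 0.39 (camera adjusted p = 0.00141, but adjusted p = 0.772 with an estimated correlation), and with library size alone 15 rose and 0 fell, with a median of 0.19. Rpl11 is an example (0.55 ± 0.09, adjusted p = 0.000287).

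ER chaperones fell (0 rose, 18 fell and 2 were not called of 20, and the same over the list alone). Their median was −0.85 (camera adjusted p = 6.52e-06, but adjusted p = 0.388 with an estimated correlation). Examples were Xbp1 (−2.11 ± 0.09, adjusted p = 3.03e-08), Manf (−1.95 ± 0.18, adjusted p = 4.14e-06) and Hyou1 (−1.78 ± 0.2, adjusted p = 1.68e-05). Amino-acid stress genes fell (4 rose, 17 fell and 3 were not called of 24, and the same over the list alone). Their median was −1.43 (camera adjusted p = 6.34e-07, but adjusted p = 0.204 with an estimated correlation). Members called included Slc7a11 (ENSMUSG00000027737, chromosome 3, 49892526 to 50443614, −6.65 ± 0.36, adjusted p = 1.5e-07), Asns (−3.74 ± 0.18, adjusted p = 5.9e-08) and Pycr1 (−4.04 ± 0.25, adjusted p = 3.15e-07). Cytokines and chemokines fell (1 rose, 13 fell and 11 were not called of 25, and the same over the list alone). Their median was −0.98 (camera adjusted p = 0.00257, but adjusted p = 0.204 with an estimated correlation). They included Cxcl5 (−5.45 ± 0.24, adjusted p = 4.17e-08), Cxcl1 (−4.2 ± 0.28, adjusted p = 4.83e-07) and Il33 (−3.03 ± 0.18, adjusted p = 1.95e-07). Mitochondrially encoded genes fell (0 rose, 6 fell and 1 was not called of 7, and the same over the list alone). Their median was −1.55 (camera adjusted p = 0.00179, but adjusted p = 0.145 with an estimated correlation). Among them were mt-Nd2 of complex I (−2.87 ± 0.22, adjusted p = 1.35e-06) and mt-Cytb (−1.6 ± 0.17, adjusted p = 1.09e-05).

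DNA replication genes went both ways (8 rose and 10 fell of 28, camera adjusted p = 0.684). Rrm2, which supplies deoxynucleotides, fell (−2.5 ± 0.24, adjusted p = 5.76e-06), and Ccne2, a cyclin of S-phase entry, rose (2.44 ± 0.17, adjusted p = 7.22e-07). Of the Mitosis genes 6 rose and 1 fell of 24 (adjusted p = 0.368), with higher Bub1 (1.14 ± 0.17, adjusted p = 0.000143). The medians of the DNA replication (0.1, or −0.11), Mitosis (0.19, or −0.02), Epithelial (0.16, or −0.05) and YAP (0.15, or −0.06) lists changed sign with library size alone. The luminal genes Esr1, the oestrogen receptor (−2.6 ± 0.18, adjusted p = 5.38e-07), and Csn3, a casein (−3.98 ± 0.32, adjusted p = 1.74e-06), fell. Mammary luminal genes had 2 rises and 5 falls of 13 (3 and 5 over the list alone, adjusted p = 0.0627). Immediate early genes had 7 rises and 4 falls of 15 (adjusted p = 0.637). Egr1 fell (−4.42 ± 0.18, adjusted p = 2.84e-08) and Ier3 rose (2.95 ± 0.11, adjusted p = 2.39e-08). Among p53 targets 7 rose and 6 fell of 17 (adjusted p = 0.222). Mdm2, which restrains p53 (1.48 ± 0.14, adjusted p = 5.13e-06), and Sesn1 (2.61 ± 0.13, adjusted p = 6.95e-08) rose. The intermediate filament gene Vim rose (1.81 ± 0.24, adjusted p = 5.71e-05), with 7 rises and 2 falls of 17 Mesenchymal genes (adjusted p = 0.112). The collagen gene Col12a1 rose (3.74 ± 0.24, adjusted p = 3.34e-07), with 11 rises and 4 falls of 27 matrix genes (adjusted p = 0.0736).

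In the remaining lists, none called, rises and falls were 4 and 3 of 10 for HIF machinery (adjusted p = 0.543), 0 and 4 of 5 for TAM genes (0.116), 4 and 3 of 19 for Epithelial genes (0.406) and 5 and 4 of 10 for Basal and myoepithelial genes (0.721). They were 3 and 11 of 25 for Interferon-stimulated genes (0.271), 6 and 7 of 17 for MHC class I presentation (0.395) and 4 and 11 of 23 for Cholesterol synthesis (0.139). They were 4 and 14 of 30 for OXPHOS nuclear genes (0.368), 2 and 1 of 6 for histones (0.637), 2 and 4 of 10 for ERBB receptors and ligands (0.297) and 5 and 3 of 16 for YAP targets (0.637). Of other cell types there were 2 and 2 of 7 for leukocyte markers (0.684), 1 and 4 of 7 for fibroblast markers (0.0627), 4 and 0 of 8 for endothelial markers (0.116) and 2 and 1 of 3 for adipocyte markers (0.443). Adjusted over the list alone, OXPHOS genes had 4 and 15, and the others were unchanged. The signs of median, mean and test differed for the HIF machinery, Basal, DNA replication and histone lists.

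The higher genes by the naming rule were the chloride channel regulator Clca2 (ENSMUSG00000036960, chromosome 3, 145070263 to 145099443, 8.71 ± 0.34, adjusted p = 2.39e-08), Tmod2 (8.21 ± 0.68), Cyp2s1 (7.47 ± 0.34, adjusted p = 5.08e-08) and Espn (6.84 ± 0.22). Next came the adhesion gene L1cam (6.49 ± 0.32, adjusted p = 7.75e-08), Mettl7b (6.13 ± 0.28), the water channel Aqp1 (13.1 to 718 CPM, 5.78 ± 0.15, adjusted p = 1.66e-09) and Atp7b (5.66 ± 0.75). The lower genes were the adhesion receptor Vcam1 (ENSMUSG00000027962, chromosome 3, 116109949 to 116129688, −7.78 ± 0.26, adjusted p = 7.31e-09), the basal regulator Trp63 (−7.78 ± 0.57, adjusted p = 9.17e-07) and Slc6a2 (−7.3 ± 0.36). Then followed Mgp, an inhibitor of calcification (ENSMUSG00000030218, chromosome 6, 136872435 to 136875823, 2730 to 26.2 CPM, −6.71 ± 0.54, adjusted p = 1.87e-06), Slc7a11, Steap4 (698 to 7.37 CPM, −6.56 ± 0.26) and Syt12 (−5.87 ± 0.27).

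Of 16767 genes, 9719 (58%) were called, 4582 higher and 5137 lower. With library size alone it was 3516 higher and 6251 lower, so that the share of higher calls moved from 47.1% to 36%. Voom with a weight per group called 12340 genes and the 6 compared libraries alone 11786. In the simulated data edgeR recovered 36.5% of 2-fold changes here and voom with weights 90.6%. The hypoxia responses of the genotypes were largely alike in sign. In both genotypes 6556 genes were called, 2899 higher and 3054 lower in both (1338 and 1575 by chance) and 603 opposite. Fold changes correlated with r = 0.571 (rho = 0.601) across genes, which are not independent replicates, and the comparisons share no library.

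**Figure D4:**
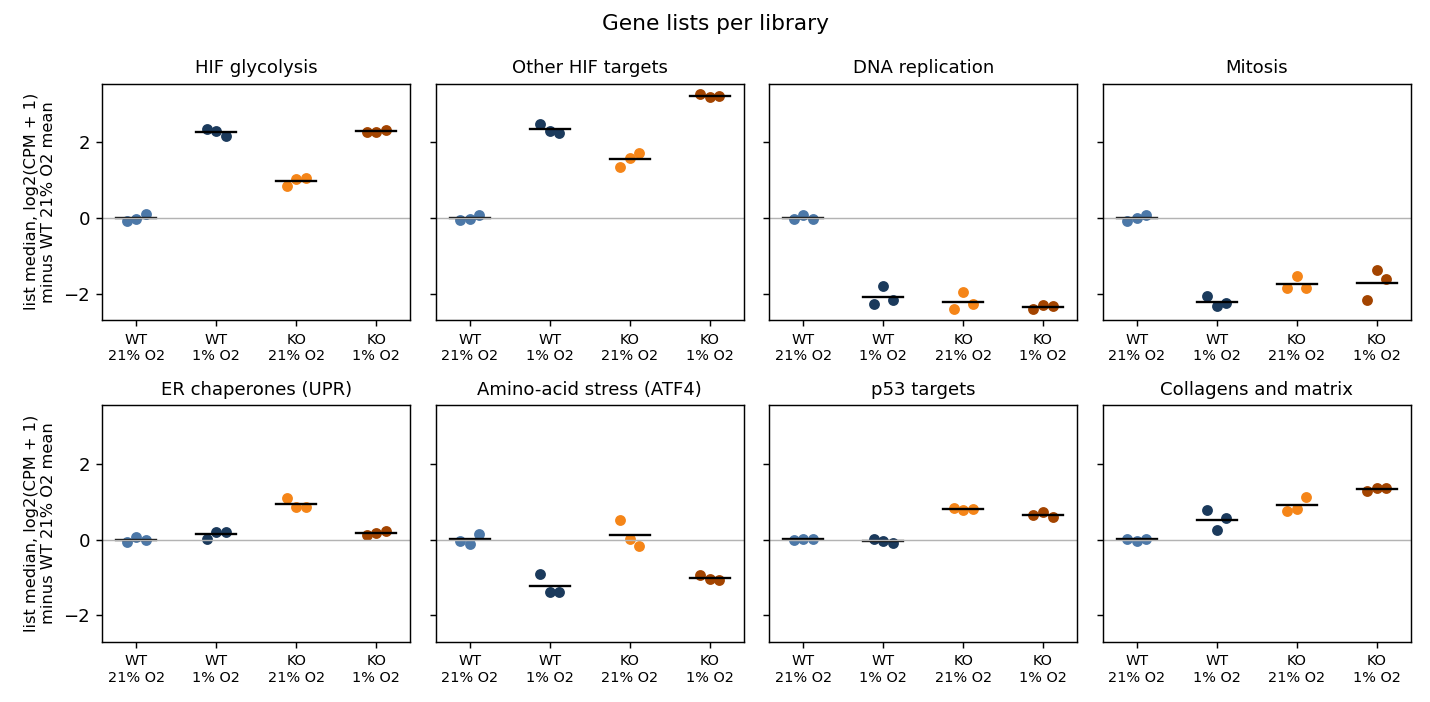
Median log2(CPM + 1) of 8 gene lists in each library (points, by group), minus the mean of AXL WT normoxia. HIF glycolysis reaches 2.164 to 2.335 in AXL WT hypoxia and 2.264 to 2.31 in AXL KO hypoxia from 0.829 to 1.062 in AXL KO normoxia, and DNA replication lies at −2.273 to −1.804 in AXL WT hypoxia and −2.407 to −1.967 in AXL KO normoxia.

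The interaction asks whether the hypoxia response differed between the genotypes, and a positive value means a response that was higher in AXL KO. HIF glycolysis genes rose less in AXL KO, from a higher starting level. DNA replication and Mitosis genes fell in AXL WT but showed no shared fall in AXL KO. ER chaperones, cytokines and several mitochondrial genes had lower responses in AXL KO. All list calls of the interaction were lost with an estimated correlation.

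HIF glycolysis had lower responses in AXL KO (0 higher, 19 lower and 5 not called of 24, or 0 and 21 over the list alone). Their median was −0.94 (camera adjusted p = 2.26e-13, but adjusted p = 0.0912 with an estimated correlation). Examples were Pfkfb3 (−2.99 ± 0.21, adjusted p = 4.49e-06) and Pfkl (−2.01 ± 0.17, adjusted p = 1.55e-05). Other HIF targets were also lower (2 higher, 12 lower and 18 not called of 32, and the same over the list alone). Their median was −0.38 (camera adjusted p = 0.00979, but adjusted p = 0.544 with an estimated correlation). Members called included P4ha2 (−1.62 ± 0.16, adjusted p = 4.65e-05) and Ankrd37 (−1.55 ± 0.2, adjusted p = 0.000198). That list's call ended without AXL WT hypoxia replicate 1 (adjusted p = 0.21). DNA replication genes had higher responses (25 higher, 0 lower and 3 not called of 28, or 27 and 0 over the list alone). Their median was 1.87 (camera adjusted p = 3.95e-28, but adjusted p = 0.0756 with an estimated correlation). Mitosis genes did so too (23 higher, 0 lower and 1 not called of 24, or 24 and 0 over the list alone). Their median was 2.39 (camera adjusted p = 5.24e-35, but adjusted p = 0.0756 with an estimated correlation). Uhrf1, which maintains DNA methylation (3.94 ± 0.32, adjusted p = 1.1e-05), and Mcm6 (2.7 ± 0.22, adjusted p = 1.08e-05) were among the former, and Kif11 (3.39 ± 0.3, adjusted p = 2.05e-05) and Nusap1 (3.41 ± 0.25, adjusted p = 6.24e-06) among the latter.

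ER chaperones had lower responses in AXL KO (0 higher, 18 lower and 2 not called of 20, or 0 and 19 over the list alone). The camera adjusted p was 5.89e-12, but adjusted p = 0.16 with an estimated correlation. They included Hspa5, the BiP gene (−3.04 ± 0.35, adjusted p = 0.000107), and Xbp1 (−2.01 ± 0.12, adjusted p = 2.82e-06). Cytokines and chemokines had them as well (1 higher, 12 lower and 12 not called of 25, or 1 and 13 over the list alone). The camera adjusted p was 8.82e-09, but adjusted p = 0.0627 with an estimated correlation. Among them were Cxcl1 (−5.23 ± 0.37, adjusted p = 4.84e-06) and Cxcl2 (−5.79 ± 0.63, adjusted p = 6.91e-05). Mammary luminal genes had lower responses too (0 higher, 7 lower and 6 not called of 13, or 0 and 8 over the list alone). The camera adjusted p was 0.00315, but adjusted p = 0.0756 with an estimated correlation. Examples were Gata3 (−1.43 ± 0.21, adjusted p = 0.000485) and Ehf (−1.19 ± 0.17, adjusted p = 0.000456). Cholesterol synthesis genes also had lower responses (0 higher, 10 lower and 13 not called of 23, and the same over the list alone). Their median was −0.35 (camera adjusted p = 0.00216, but adjusted p = 0.526 with an estimated correlation). Members called included Cyp51 (−1.41 ± 0.16, adjusted p = 8.71e-05).

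Mitochondrially encoded genes had lower responses (0 higher, 4 lower and 3 not called of 7, and the same over the list alone). Their median was −0.79 (camera adjusted p = 0.0349, but adjusted p = 0.16 with an estimated correlation). An example was mt-Nd2 (−2.02 ± 0.3, adjusted p = 0.000511). The call ended without AXL WT hypoxia replicate 3 (adjusted p = 0.0578) or AXL KO hypoxia replicate 1 (0.0547). Ribosomal proteins had higher responses (21 higher, 0 lower and 11 not called of 32, or 28 and 0 over the list alone). Their median was 0.44 (camera adjusted p = 7.9e-06, but adjusted p = 0.544 with an estimated correlation). Rps2, for example, had a difference of 0.93 ± 0.14 (adjusted p = 0.000711). Immediate early genes had lower ones (1 higher, 8 lower and 6 not called of 15, or 1 and 9 over the list alone). Their median was −0.71 (camera adjusted p = 0.00216, but adjusted p = 0.16 with an estimated correlation). Examples were Egr1 (−2.53 ± 0.23, adjusted p = 2.27e-05) and Atf3 (−2.83 ± 0.37, adjusted p = 0.000235). Their call ended without AXL WT hypoxia replicate 1 (adjusted p = 0.125). Fibroblast markers were lower (0 higher, 3 lower and 4 not called of 7, or 2 and 3 over the list alone). Their median was −2.14 (camera adjusted p = 0.00587, but adjusted p = 0.0756 with an estimated correlation). Members called included Pdgfrb (−3.55 ± 0.25, adjusted p = 4.84e-06) and Pdgfra (−2.16 ± 0.26, adjusted p = 0.000123).

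In the remaining lists, none called, higher and lower responses were 0 and 3 of 10 for HIF machinery (adjusted p = 0.208), 0 and 2 of 5 for TAM genes (0.057), 2 and 6 of 17 for Mesenchymal genes (0.208) and 3 and 1 of 19 for Epithelial genes (0.238). They were 2 and 3 of 10 for Basal and myoepithelial genes (0.0863), 4 and 9 of 27 for matrix genes (0.118), 5 and 1 of 25 for Interferon-stimulated genes (0.221) and 1 and 3 of 17 for MHC class I presentation (0.457). They were 3 and 8 of 24 for Amino-acid stress (0.0681), 1 and 4 of 30 for OXPHOS nuclear genes (0.242) and 0 and 1 of 6 for histones (0.703). They were 0 and 3 of 10 for ERBB receptors and ligands (0.43), 3 and 4 of 16 for YAP targets (0.991) and 5 and 5 of 17 for p53 targets (0.658). Of other cell types there were 0 and 1 of 7 for leukocyte markers (0.403), 1 and 0 of 8 for endothelial markers (0.658) and 0 and 0 of 3 for adipocyte markers (0.991). Adjusted over the list alone, Mesenchymal genes had 3 and 6, MHC genes 0 and 2, Amino-acid stress 4 and 8, OXPHOS 0 and 2 and p53 targets 8 and 5. The medians of the MHC genes (−0.03, or 0.06), ERBB genes (−0.08, or 0.01) and YAP targets (−0.07, or 0.04) changed sign with library size alone, and the signs of median, mean and test differed for the YAP, p53, leukocyte and adipocyte lists. The p53 target Perp had a higher response in AXL KO (1.88 ± 0.21, adjusted p = 7.74e-05), and Mertk (−2.33 ± 0.23, adjusted p = 4.63e-05) and Hif1a (−1.48 ± 0.22, adjusted p = 0.000596) had lower ones.

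By the naming rule the higher responses in AXL KO were those of Cyp2s1 (7.19 ± 1.14, adjusted p = 0.000856), the secreted factor gene Fam19a5 (ENSMUSG00000054863, chromosome 15, 87544299 to 87759364, 6.3 ± 0.31, adjusted p = 1.64e-06) and Lce1g (4.78 ± 1.39, adjusted p = 0.0238). Next came L1cam (ENSMUSG00000031391, chromosome X, 73853778 to 73896105, 4.55 ± 0.39, adjusted p = 1.51e-05), the peptidase Dpp7 (4.48 ± 0.56, adjusted p = 0.000189) and Tspan15, which has only 2 counts in AXL WT hypoxia (4.71 ± 0.52, adjusted p = 7.62e-05). The Cyp2s1 call ended without AXL WT normoxia replicate 2 (adjusted p = 0.0939), and that of Lce1g without AXL KO normoxia replicate 1 (0.0536) or 3 (0.0648) or AXL KO hypoxia replicate 1 (0.0562), without a filter (0.116) and with limma-voom (0.059). The lower responses were those of the oestrogen-binding receptor gene Gper1 (ENSMUSG00000053647, chromosome 5, 139423151 to 139427800, −10.48 ± 0.81, adjusted p = 8.14e-06), the collagenase Mmp13 (−9.41 ± 1.11, adjusted p = 0.00012) and Ogn (−8.64 ± 1.68, adjusted p = 0.00305). The Ogn call ended with limma-voom (−6.97, adjusted p = 0.0533) and without AXL WT hypoxia replicates 2 and 3 (−2.84, adjusted p = 0.0968), and that of Tspan15 with a weight per group (adjusted p = 0.074). Then followed Trp63 (ENSMUSG00000022510, chromosome 16, 25683763 to 25892102, −8.6 ± 1.45, adjusted p = 0.00127), Cxcl5 (ENSMUSG00000029371, chromosome 5, 90759360 to 90761624, −7.65 ± 0.31, adjusted p = 3.43e-07) and Matn4 (−7.32 ± 0.51, adjusted p = 4.84e-06). Few counts in a group limit several of these values. Cyp2s1 had 6 counts in each AXL WT group, and Trp63 had 4 in AXL WT normoxia and 6 in AXL WT hypoxia. Mmp13 had 5 in AXL KO hypoxia, and Matn4 had 8 and Ogn 11 in AXL WT normoxia. Lce1g and Dpp7 each had 13 in AXL KO normoxia. In AXL WT hypoxia Mmp13 (15.9 ± 15.5 CPM), Ogn (12.5 ± 15.2), Lce1g (54.6 ± 64.7) and Gper1 (217 ± 176) were uneven.

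Of 16767 genes, 4830 (28.8%) were called, 2264 with higher and 2566 with lower responses in AXL KO. The interaction includes AXL WT hypoxia, whose wide spread makes the p-values too small here too. In data simulated with the spread of each group, 2.95% of unchanged genes lay under its p cutoff of 0.0144. The balance turned with library size alone (2650 higher and 2162 lower) and with limma-voom (2755 and 2472). Voom with a weight per group called 4842, and the count was 8417 without AXL WT hypoxia replicate 1 and 6655 without replicates 2 and 3, which leaves 1 library in that group.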

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

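Of the tests in this part, the splits of the samples and the scaling test were planned, and those of chromosome content, genes read in a single genotype, leukocytes, mixed cells, HIF strength, left-out libraries and the AXL KO level in 21% oxygen were chosen only after the result was seen.

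The hypoxia response differed between the genotypes in 4830 genes (edgeR interaction), and tests of this difference flagged the genes and lists of this paragraph. The genes named by rule were Cyp2s1 (7.19), Fam19a5 (6.3), Lce1g (4.78), Tspan15 (4.71), L1cam (4.55), Dpp7 (4.48), Gper1 (−10.48), Mmp13 (−9.41), Ogn (−8.64), Trp63 (−8.6), Cxcl5 (−7.65) and Matn4 (−7.32), as log2 differences of the responses. Several of these genes have few counts in a group, as given above. The lists flagged by the camera test of the interaction, with adjusted p, were HIF glycolysis (2.26e-13), Other HIF targets (0.00979), Mammary luminal (0.00315), Cytokines and chemokines (8.82e-09), DNA replication (3.95e-28), Mitosis (5.24e-35), Cholesterol synthesis (0.00216), ER chaperones (5.89e-12), Mitochondrially encoded (0.0349), Ribosomal proteins (7.9e-06), Immediate early (0.00216) and Fibroblast markers (0.00587), and none of them passed 0.05 with an estimated correlation.

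With 3 libraries against 3, the 10 possible splits are too few for a share under 0.05. Real counts on the 6 compared libraries were 7696 for AXL KO against WT in hypoxia, 12610 in normoxia, 7600 for hypoxia in AXL WT and 11786 in AXL KO, and the highest count of another split was 0 in each, so that 1 of 10 splits reached the real count. For the interaction the real count of 4830 was reached by 1 of 100 drawn splits, the real one, and the highest other count was 4811. The 14 other splits that kept the genotypes apart at a single oxygen level called 238 to 4811 genes, and the 85 that mixed them at both called 0. The genotype difference itself thus sets these counts, and they say nothing on chance.

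Genotype differences were alike in sign at both oxygen levels (r = 0.826), which may reflect loss of AXL or other differences between the cells used as AXL WT and AXL KO. The chromosome medians of AXL KO against WT had an SD of 0.265 in hypoxia, above the highest of 1000 shuffles (0.0764), and they correlated between oxygen levels with r = 0.98, which fits a difference in chromosome content. Loss of AXL alone is argued against for these shifts of whole chromosomes, as their SD was at least 4.29 times that of the hypoxia contrasts, of which the one in AXL KO also lay just above its shuffles (0.0618 against 0.0601). At both oxygen levels 70 genes lay over 10 CPM in a genotype and under 0.1 CPM in the other, among them Cdkn2a and Cdkn2b with 0 counts in AXL KO, and Xist stood at 0.353 CPM or less in AXL WT and 416 to 811 CPM in AXL KO. For such single genes loss of AXL and a separate history of the cells cannot be told apart, since the labels name neither another knockout line nor a rescue, and how much of the difference belongs to AXL stays open.

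The AXL WT hypoxia libraries differed from each other far more than those of other groups, with Csf1r at 5.41, 145 and 41.1 CPM, which might come from other cells or from unequal hypoxia. Leukocytes are argued against, because the largest rise of 7 other leukocyte genes was 0.0462 CPM (Fcer1g) against 63.9 CPM for Csf1r. AXL KO cells mixed in are argued against, because genes seen in AXL KO and without a count in AXL WT normoxia reached a median of 0% of their AXL KO hypoxia level. A different strength of hypoxia stays open, because between the 3 libraries the HIF glycolysis level ranged over 0.171 log2 units and that of Other HIF targets over 0.259, but that of HIF machinery over 0.546. RNA quality, culture density and time in hypoxia were not tested and stay open too.

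DNA replication and Mitosis genes fell in hypoxia in AXL WT but showed no shared fall in AXL KO. That 1 or 2 libraries made the difference is argued against, as each of the 3 AXL WT hypoxia libraries lay at −1.8 log2 units or lower in both lists, and scaling is argued against, as the lower of the list medians of the interaction was 1.97 with library size alone. A level in AXL KO that is already low in 21% oxygen fits: the DNA replication level was −2.09 in AXL WT hypoxia, −2.21 in AXL KO normoxia and −2.35 in AXL KO hypoxia relative to AXL WT normoxia, and AXL KO normoxia lay at least 0.789 times as far under AXL WT normoxia as AXL WT hypoxia did in both lists. The interaction may therefore reflect a low start in AXL KO more than a different response to hypoxia. Whether AXL KO cells grew more slowly before hypoxia was not measured and stays open.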

How the results depend on the processing

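Of 612 results for named genes, 562 kept direction and call under every alternative tested, 50 were weaker under some and 0 reversed. Of the 50, 34 were weaker under a planned setting and 16 only under the pair of settings chosen after seeing the data. The strict filter held 544 of the 612, and a minimum fold was applied to counts only. Naming by large fold or small p in the same libraries favours keeping a call, so these counts do not describe all genes. Axl stayed at −8.16 to −7.86 in hypoxia and −8.44 to −8.09 in normoxia. Calls with a fold of at least 2 were 6336 for AXL KO against WT in hypoxia, 5916 in normoxia, 5911 for hypoxia in AXL WT, 5359 in AXL KO and 2938 for the interaction, fewer because the threshold is stricter. With DESeq2 the counts were 10792, 10326, 10263, 10104 and 5771, with limma-voom 10530, 10252, 10210, 9885 and 5227, and with voom and a weight per group 8209, 12914, 7607, 12340 and 4842. With each library left out in turn they were 9688 to 12564, 8873 to 9121, 9013 to 11720, 8288 to 8834 and 3582 to 8417, and the cause of the last range was not tested. The interaction calls of Ogn, Tspan15 and Lce1g ended under some settings, as given above, and the cause was not tested.

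The number of lists called depended on the test: with camera at the preset correlation, camera at an estimated one and fry, which does not compare a list with the other genes, it was 3, 0 and 19 for AXL KO against WT in hypoxia, 12, 0 and 26 in normoxia, 9, 2 and 17 for hypoxia in AXL WT, 7, 0 and 22 in AXL KO and 12, 0 and 20 for the interaction. In AXL KO against WT in hypoxia it was 2 to 5 with libraries left out, 5 without AXL KO hypoxia replicate 1. Genes called at both oxygen levels for the genotype numbered 5358 to 7548 and genes called in both genotypes for hypoxia 5152 to 6889 with the strict filter, RLE, library size alone and the block. Deviations of same-numbered libraries from their group means had r of −0.065 to 0.142, with no other pairs computed, so pairing stays open. With the number as a block the counts were 10425, 9915, 9875, 9582 and 4521. The block ended the call of Collagens and matrix genes in AXL KO against WT in hypoxia (adjusted p = 0.122) and added Epithelial genes in normoxia (0.0454). Depth limits genes with few counts, whose folds are given as floors or ratios.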

Other observations

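The genes in this part were picked after their values were seen, while the edgeR contrasts that test them were planned. The heat shock genes Hspa4l, Hsph1 and Hspa1b rose in hypoxia in both genotypes: Hspa4l by 3.62 ± 0.19 in AXL WT (adjusted p = 7.57e-08) and 2.94 ± 0.18 in AXL KO (adjusted p = 3.3e-07), Hsph1 by 3.51 ± 0.19 (adjusted p = 7.6e-08) and 3.86 ± 0.19 (adjusted p = 6.87e-08), and Hspa1b by 4.34 ± 0.34 (adjusted p = 1.12e-06) and 2.7 ± 0.32 (adjusted p = 2.76e-05). Ptgs2 (ENSMUSG00000032487, chromosome 1, 150100031 to 150108227) rose in hypoxia by 6.77 ± 0.37 in AXL WT (adjusted p = 1.03e-07) and 1.71 ± 0.3 in AXL KO (adjusted p = 0.000454), a difference of −5.06 ± 0.43 (adjusted p = 1.56e-05). Nos2 rose in AXL KO as well (3.87 ± 0.25, adjusted p = 4.25e-07), less than in AXL WT (difference −6.08 ± 0.45, adjusted p = 6.24e-06). Spp1 was higher in AXL KO in hypoxia too (1.64 ± 0.13, adjusted p = 9.13e-07).

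Xist, the RNA of the inactive X chromosome, stood at 416 to 811 CPM in the AXL KO libraries and at 0.353 CPM or less in the AXL WT libraries (ENSMUSG00000086503, chromosome X, 103460375 to 103483217; 13.02 ± 0.45 in normoxia, adjusted p = 8.16e-10). Cdkn2a and Cdkn2b had 0 counts in all 6 AXL KO libraries, while their neighbours on chromosome 4 were read there: Mtap (ENSMUSG00000062937, 89137122 to 89181081) at 458 to 574 CPM in normoxia and 118 to 137 CPM in hypoxia, Klhl9 at 82.4 to 123 CPM and Focad at 14.9 to 28.7 CPM. Erbb2 stood at 1120 to 1340 CPM in AXL WT and 500 to 651 CPM in AXL KO in normoxia, but edgeR, with a spread shared by all groups, did not call it (−1.13 ± 0.72, adjusted p = 0.194). It was not called in the other contrasts either (−0.54 ± 0.71, adjusted p = 0.525 for AXL KO against WT in hypoxia).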
